A study of Physcomitrium patens with 5 samples.

How the data were processed

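DNA methylation was measured by bisulfite sequencing in gametophores, the leafy shoots of the moss Physcomitrium patens. Bisulfite converts unmethylated cytosines so that they are read as thymines, while methylated cytosines stay cytosines. There were 5 libraries, 1 each from hydrated, moderately dehydrated, severely dehydrated, partially rehydrated and fully rehydrated plants. The labels call the moderately dehydrated library mild in 1 place and moderate in another, and it is called moderate dehydration here. Per the labels' protocols, DNA was sheared by sonication, ligated to methylated adaptors, treated with a bisulfite conversion kit, amplified by PCR and size-selected. Each state had 1 library, so no difference between states could be set against the spread between replicates.

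The data analysed here were the authors' deposited table of their own comparisons, with 225 genes and 4 columns, each comparing the hydrated library with 1 other library. Per the file headers, each entry gives the part of the gene (the 2 kb upstream, the body, or the 2 kb downstream), the start and end of a differentially methylated region, a methylation ratio and a direction. The authors' values are log2 ratios of methylation levels. All 267 entries had a sign that matched their direction word, a size of at least 1 on the log2 scale, and an end at least 200 bases after the start. The aligner, the caller of the regions, its thresholds, the genome build, the cytosine context and the coverage are not given in the sources used here. The depth behind each value is therefore unknown, and no counting interval is given for a single ratio. Gene identifiers and scaffold coordinates are printed as the table gives them. The reference gene table at hand held 0 of these identifiers, and gene names are the orthology definitions and gene ontology terms in the authors' table. Some definitions end in a further orthology identifier, which may stand for another protein. Among them are those of the genes named here as RPB1, PRP4, HERC4, MOB1, p-coumarate 3-hydroxylase and some RPS2-like genes. Names and descriptions follow the printed definition only, and the identity of these genes is not settled.

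Each ratio was an exact fraction of 2 whole-percent levels, within a relative tolerance of 1e-09, where a level of 0 had been replaced by 0.001. Both levels were taken back from the ratio only where a single pair of whole percents gave it, which was the case for 82 of 224 regions. This needs a high level or a level of 0, so the recovered levels over-represent such regions. The table does not say which library is the numerator. On scaffold 84 (35988 to 36218) and scaffold 439 (50137 to 50554), regions with identical ends were listed in 2 comparisons. With the hydrated library as denominator, 2 and 6 hydrated levels could give both ratios, and with it as numerator 0 could. A positive value is therefore read as higher methylation than in the hydrated library.

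A region linked to several genes was counted once per comparison, which left 224 regions. The design had planned to count every row. Counting distinct regions, and using the log2 ratio where a difference of levels had been planned, were choices made after the table was seen. Shares of regions have exact Clopper-Pearson 95% intervals, medians have order-statistic 95% intervals, and both cover counting error over listed regions only. The share higher was tested with an exact two-sided binomial test against equal shares, and differences between comparisons with Fisher's exact test, two-sided. Adjusted p-values are Benjamini-Hochberg over the 4 comparisons, the 6 pairs of comparisons, or the lists or terms tested. Regions are not replicates, so each p describes the lists drawn from these libraries and not the states of the plants. Positions were compared by permutation tests with 100000 resamples within classes of scaffold number. The tests between comparisons and those of positions and of levels of 0 were chosen after the table was seen.

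The gene lists, the tests on them, the binomial test of direction and the rule for naming genes were fixed before the data were examined. There were 19 lists of keyword patterns: transposable elements, late embryogenesis and seed proteins, hormone signalling, redox and detoxification, chaperones, osmolyte and sugar metabolism, photosynthesis, ribosome and translation, kinases and phosphatases, transcription factors, chromatin, DNA repair and replication, RNA processing, transport, cell wall, cytoskeleton and trafficking, ubiquitin and proteolysis, lipid metabolism, and resistance proteins. Lists with at least 5 gene and region entries in a comparison, and ontology terms with at least 5 genes, were tested by Fisher's exact test of higher against lower members, with the other annotated entries or genes of that comparison as background. A gene with several regions enters a list test once per region, and with 1 value per gene 3 of the 7 list tests remained. Genes that share a region each enter the list and term tests, so their entries are not independent. Some patterns also match inside other words, such as RING in transferring, so counts on the orthology definition alone are given where they differ. Those counts can still hold such matches. The rule named, per comparison, the 10 annotated genes with the largest rise, the 10 with the largest fall, and the 2 largest changes in each list. It gave 18 genes for moderate dehydration, 20 for severe dehydration, 19 for partial rehydration and 32 for full rehydration.

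The recovery of levels was tested on 2000 simulated level pairs, of which 48.9% had a unique solution, and 100% of those were right. The simulated pairs had the whole-percent levels and the replacement of 0 that the recovery assumes. The 100% therefore checks the calculation, and not whether the deposited levels were formed in this way. Of 2000 unrounded ratios, 0 were accepted as fractions of whole percents. In simulations of the list test in full rehydration, with its 77 annotated entries from 70 genes, a planted list of 12 entries with 11 lower passed before adjustment in 90% of 200 draws, and an unplanted list in 4%. The lists tested in the data held 5 to 18 entries, most of them fewer than 12, and some were in partial rehydration. The simulation therefore does not give the power of those tests. Calculations used Python 3.11.15, NumPy 2.4.6 and SciPy 1.17.1. Alternatives to these choices were every gene and region entry, 1 value per gene, annotated genes alone, regions whose recovered levels differ by at least 20 points, a pseudocount of 0.01, and, chosen after seeing the data, merged overlapping regions, regions without a level of 0, regions within a shared span, recovered levels without a pseudocount, and patterns at word starts.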

Results

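DNA methylation was compared between the hydrated library and 4 other libraries taken in the course of drying and rewetting of gametophores. The authors' deposited table listed 225 genes with a differentially methylated region in the gene body or within 2 kb of it. These genes held 224 regions on 163 scaffolds, where a region listed in 2 comparisons counts in each. Of the regions, 30 came from moderate dehydration, 22 from severe dehydration, 40 from partial rehydration and 132 from full rehydration. Of the 225 genes, 209 were listed in 1 comparison and 16 in 2. An annotation was given for 127 genes, and 98 had none. There were no replicates, and the depth of the libraries is unknown. A region is called higher or lower by its methylation relative to the hydrated library, and every listed region differed at least 2-fold in the authors' values.

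In moderate dehydration, 38 genes were listed, with genes for translation and kinases among the highest ratios and RPB1 and a lipid enzyme among the lowest. In the authors' deposited table, the gene for eIF-3 subunit 1 (Pp1s201_55V6), a translation initiation factor, had a log2 ratio of 2.91 in its downstream flank. The ribosomal protein S4e gene (Pp1s119_107V6) stood at 2.50 in its body in the authors' deposited table, on scaffold 119 from 908306 to 908530. All 3 genes of the ribosome and translation list in this comparison were higher, as were 15 of its 22 annotated genes, and the list was too small for the planned test. A pair of neighbouring genes with kinase terms, Pp1s210_4V6 and Pp1s210_5V6, shared a downstream region on scaffold 210 (25919 to 26272) with a log2 ratio of 3.22 in the authors' deposited table. The small nuclear ribonucleoprotein D3 gene (Pp1s33_44V6), part of the splicing machinery, stood at 2.36, and the upstream flank of the excision repair gene RAD23 (Pp1s286_52V6) was 4-fold higher, in the authors' deposited table. On the lower side, the authors' deposited table gave log2 ratios of -3.46 upstream of RPB1 (Pp1s208_15V6), the largest subunit of RNA polymerase II, and -3.12 upstream of phosphatidylserine synthase 2 (Pp1s159_14V6), a membrane lipid enzyme. The region downstream of the RNA helicase gene DDX42 (Pp1s358_35V6) went from a recovered level of 12% in the hydrated library to a level listed at 0.

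Of the 30 regions of moderate dehydration, 21 were higher and 9 lower, or 70% higher (95% exact interval 50.6 to 85.3). The exact binomial test gave p = 0.0428 and an adjusted p of 0.0855, so the excess of higher regions did not hold after correction. The median size of the log2 ratio was 1.49 (95% interval 1.17 to 2.36). By gene part, 24 entries lay upstream, 3 in the body and 12 downstream.

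In severe dehydration, 30 genes were listed, with a glutathione S-transferase and ubiquitin enzymes on the lower side and phenylalanine ammonia-lyase and a peroxidase on the higher side. The largest fall in the authors' deposited table was -3.46, downstream of a glutathione S-transferase gene (Pp1s117_152V6), a detoxification enzyme, on scaffold 117 from 956372 to 956607. The authors' deposited table also gave -2.46 in the body of an axonemal dynein heavy chain gene (Pp1s42_115V6) and -2.17 downstream of the ribosomal protein S2e gene (Pp1s411_32V6). Upstream of the ubiquitin ligase gene HERC4 (Pp1s126_183V6), recovered levels were 59% in the hydrated library and 20% after severe dehydration. The autophagy gene ATG12 (Pp1s102_138V6) and its neighbour for a ubiquitin-conjugating enzyme (Pp1s102_139V6) shared a region that was 2-fold lower in the authors' deposited table. On the higher side, the authors' deposited table gave 1.29 for a region between phenylalanine ammonia-lyase genes (Pp1s100_51V6 and Pp1s100_53V6), the entry enzyme of phenylpropanoid synthesis, and 1.14 upstream of a myo-inositol transporter gene (Pp1s159_1V6). A peroxidase gene (Pp1s9_70V6) stood at 1.09 in its body in the authors' deposited table. Downstream of the ribosomal protein S21e gene (Pp1s287_34V6), the level was 27% in the hydrated library and 67% after severe dehydration.

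The 22 regions of severe dehydration divided into 12 higher and 10 lower, or 54.5% higher (95% exact interval 32.2 to 75.6; exact binomial p = 0.832, adjusted p = 0.832). The median size was 1.57 on the log2 scale (95% interval 1.14 to 2.22). A level of 0 was found in 0 of the 22 regions, for which the 95% exact interval reaches 15.4% and the limit of 3 counts in 22 is 13.6%. All 4 genes of the ubiquitin and proteolysis list were lower and all 4 of the kinase and phosphatase list were higher, against 11 higher and 10 lower of all 21 annotated genes, and neither list reached the size for a test. By orthology definition, the lower ubiquitin genes were those for HERC4 and the conjugating enzyme, and the other members of that list matched a pattern elsewhere in their annotation. In the kinase and phosphatase list, Pp1s210_4V6 and Pp1s210_5V6 shared a region, and Pp1s181_95V6 is annotated as a dihydroxyacetone kinase.

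Partial rehydration differed from the other states in its list, where most regions were lower than in the hydrated library. The largest fall of an annotated gene in the authors' deposited table was -3.52, downstream of a phosphate transporter-like gene (Pp1s188_14V6) on scaffold 188 from 174732 to 175055. The authors' deposited table gave -2.63 downstream of the gene for subunit 1 of the origin recognition complex (Pp1s56_182V6), which marks replication origins, and -1.87 downstream of an mRNA methyltransferase gene (Pp1s41_79V6). A region at cytosolic dynein genes (Pp1s92_56V6 and Pp1s92_57V6) stood at -1.62, and the body of a chalcone synthase gene (Pp1s365_24V6), a flavonoid enzyme, at -1.44, in the authors' deposited table. In the authors' deposited table, the eIF-2 beta subunit gene (Pp1s81_161V6) had a log2 ratio of -1.42, a pectinesterase gene (Pp1s258_34V6) -1.38 and the photosystem II gene PsbW (Pp1s71_61V6) -1.23. All 5 entries of the resistance protein list, from 4 genes, were lower, as were 18 of the 23 other annotated entries (Fisher's exact p = 0.550, adjusted p = 1). This test decides nothing about a lean of the list towards lower. With most other entries lower, a list of 5 could not pass even with every entry lower.

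Of the 40 regions of partial rehydration, 35 were lower and 5 higher, or 87.5% lower (95% exact interval 73.2 to 95.8), past the exact binomial test (p = 1.38e-06, adjusted p = 5.53e-06). In the gene bodies, 11 of 12 entries were lower, or 10 of 11 loci once overlapping regions were merged. The higher regions included the upstream flank of a peptidase gene (Pp1s439_5V6) at 2.91, the region by a casein kinase 1 gene (Pp1s471_4V6) at 1.34 and the body of the p-coumarate 3-hydroxylase gene (Pp1s15_392V6) at 1.03, in the authors' deposited table. For the last, an enzyme of phenylpropanoid synthesis, recovered levels were 27% and 55%. The share of regions higher was 57.5 percentage points larger in moderate dehydration (Fisher's exact adjusted p = 3.01e-06), 42.0 points larger in severe dehydration (adjusted p = 0.00152) and, as partial minus full rehydration, stood at -43.6 points (adjusted p = 3.01e-06). The other 3 pairs of comparisons did not pass (Fisher's exact adjusted p = 0.459, 0.327 and 1). The median size was 1.37 on the log2 scale (95% interval 1.23 to 1.48).

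**Figure D1:**
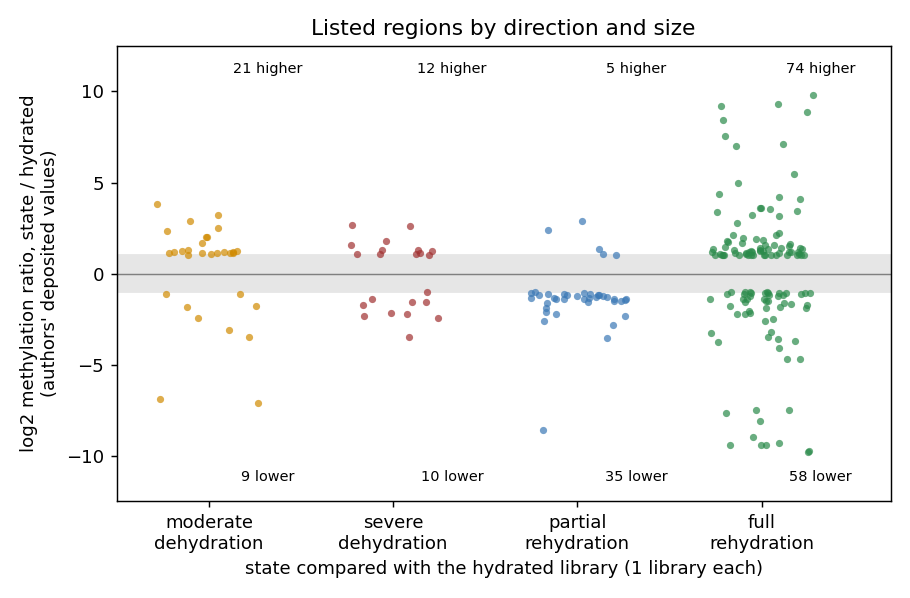
Each point is 1 region from the authors' deposited table, by the state compared with the hydrated library (x axis) and its log2 methylation ratio (y axis). Grey marks sizes under 1, where no region is listed, and the counts are of regions higher and lower: 35 of 40 partial rehydration regions lie below 0, and the points farthest from 0 have a level of 0 in 1 library, so that their height is set by the 0.001 that stands for it.

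Full rehydration had the longest list, with 127 genes, and it held regions with a methylation level of 0 in either library. Downstream of a 1-alkyl-2-acetylglycerophosphocholine esterase gene (Pp1s194_151V6), the level was listed at 0 in the hydrated library and 89% after full rehydration. Upstream of a cyclin-dependent kinase gene (Pp1s214_1V6), a cell cycle regulator, it was 0 and 46%, and upstream of the splicing factor 3B subunit 3 gene (Pp1s197_41V6) 0 and 19%. In the other direction, the sucrose-phosphate synthase gene (Pp1s131_3V6), which makes the precursor of sucrose, was at 67% in the hydrated library and listed at 0 after full rehydration in its upstream flank on scaffold 131 from 27732 to 27967. The gene for the splicing kinase PRP4 (Pp1s250_28V6) went from 18% to 0 in its body, and the upstream region of an RPS2-like resistance gene (Pp1s18_7V6) from 27% to 0. No fold is given for such regions.

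Among regions with both levels above 0, an auxin response factor gene (Pp1s86_4V6) was at 83% in the hydrated library and 18% after full rehydration, the EREBP-like gene Pp1s120_13V6 at 67% and 4%, and the RNA helicase gene DDX5 (Pp1s35_3V6) at 70% and 17%. A phosphatase gene (Pp1s304_50V6) was at 4% and 69%, and a pyruvate dehydrogenase E2 gene (Pp1s291_55V6), part of the entry to the citrate cycle, at 25% and 71%. In the authors' deposited table, log2 ratios were 3.62 upstream of the protease adaptor gene ClpS (Pp1s40_52V6), 3.58 in the body of a cellulose synthase A gene (Pp1s15_30V6), and -3.77 upstream of a ubiquitin-conjugating enzyme gene (Pp1s460_7V6). The authors' deposited table gave -1.38 upstream of a SWI/SNF chromatin remodeller gene (Pp1s9_14V6) and -1.11 downstream of the light-harvesting gene LHCB5 (Pp1s628_3V6).

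**Figure D2:**
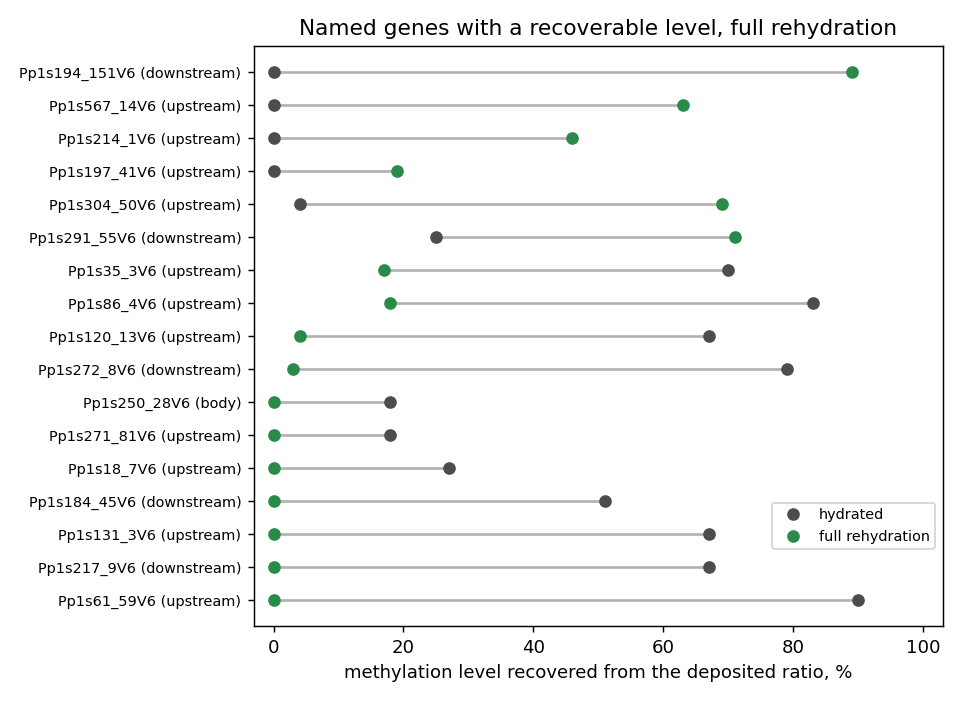
Methylation level in percent (x axis) of named genes (y axis) whose levels could be recovered from the authors' deposited table, in the hydrated library (grey) and after full rehydration (green). Each dot is 1 library, a line joins both, and the levels run from 0 to 90%.

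Of the 132 regions of full rehydration, 74 were higher and 58 lower, or 56.1% higher (95% exact interval 47.2 to 64.7), a split within chance (exact binomial p = 0.191, adjusted p = 0.255). Among regions linked to an annotated gene, 45.8% were higher, against 68.3% of the rest (Fisher's exact p = 0.0135, adjusted p = 0.0538). The direction of the split thus turned in the annotated regions, but the difference did not hold after adjustment. Overlapping regions were counted separately here, and those of the unannotated genes Pp1s202_4V6 and Pp1s226_12V6 were all higher. This contrast was not repeated with overlapping regions merged. In gene bodies, 18 entries were higher and 7 lower, but with overlapping regions merged these were 12 loci higher and 7 lower, since genes such as Pp1s202_4V6 and Pp1s226_12V6 held several overlapping regions. The median size was 1.58 on the log2 scale (95% interval 1.38 to 1.85). A level of 0 was found in 19 regions (14.4%), against 3 of the 92 regions of the other comparisons (3.26%; Fisher's exact p = 0.00569).

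Across comparisons, 16 pairs of listings shared a gene, 12 of them in the same direction. Moderate and severe dehydration shared 3 genes, among them the kinase genes Pp1s210_4V6 and Pp1s210_5V6, at 3.22 and 2.66 in the authors' deposited table, and the ribosome biogenesis ATPase gene (Pp1s12_28V6), at 1.24 and 1.58. Moderate dehydration and full rehydration shared 4, among them the F-type ATPase beta gene (Pp1s154_66V6), at 1.17 and 1.14, in the authors' deposited table. Partial and full rehydration shared 8, with 4 in the same and 4 in the opposite direction. Of 10 pairs of regions that shared at least 1 base, 8 (80%) had the same sign. Levels drawn independently from the recovered ones and set against 1 shared hydrated level gave 82.6% over the 149341 pairs, of 400000 drawn, in which both reached the size of a listed region. Of the 82 regions behind these levels, 63 came from full rehydration, and regions that overlap in part need not share a hydrated level. The 82.6% is therefore not a chance level for the 80%. The number of genes tested by the authors is not given, so overlap by chance was not computed.

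By gene group over all comparisons, kinases and phosphatases were the largest list, with 22 genes of which 13 were listed as higher only, 8 as lower only and 1 as both. By orthology definition alone this list had 10 genes, 5 higher and 5 lower. Ribosome and translation genes numbered 10, with 5 higher and 5 lower by either match. RNA processing had 9 genes (7 higher, 2 lower), or 2 and 1 by orthology definition. Redox and detoxification had 8 (4 and 4), or 1 and 2 by definition, and transport 7 (4 and 3), or 4 and 1. The higher transport genes by definition include the ribosome biogenesis ATPase gene (Pp1s12_28V6), matched through the word ATPase. Lipid metabolism had 7 (3 and 4), or 1 and 1 by definition. The lower of these was a hydroxyacylglutathione hydrolase gene (Pp1s446_8V6), matched through acyl inside its name. Of 16 cytoskeleton and trafficking genes, 6 were higher and 10 lower, and of those with a matching orthology definition 1 and 5. The lower 5 include the SWI/SNF remodeller gene Pp1s9_14V6, matched through the word actin. They also include the dynein genes Pp1s92_56V6 and Pp1s92_57V6, which share a region. Ubiquitin and proteolysis had 12 genes (4 higher, 8 lower), or 1 and 3 by orthology definition. Photosynthesis had 4 genes (1 higher, 3 lower), or 0 and 3 by definition, and DNA repair 4 (2 and 2), or 0 and 2. The DNA repair genes matched by definition were the RNA helicase genes DDX42 and DDX5, through the word helicase. The excision repair gene RAD23, which was higher, was not matched by its definition. Chromatin had 4 genes (1 higher, 3 lower) by either match, and the lower ones included the mRNA methyltransferase gene Pp1s41_79V6. The resistance list had 5 genes, of which 3 were listed as lower only and 2 as both. Hormone signalling had 2 genes, both lower, and cell wall had 1 higher and 1 lower. Sugar metabolism and transcription factors each had 1 higher and 1 lower, or 0 and 1 by definition. Transposable elements, late embryogenesis proteins and chaperones had 0 genes. Of 7 tests of a list within a comparison, 0 passed Fisher's exact test after adjustment and 0 before it (smallest p 0.189). List size fixed part of this outcome. Both lists tested in partial rehydration, ubiquitin and resistance, could not have passed towards lower. In full rehydration, the transport and resistance lists of 5 entries and the redox list of 6 could not have passed after adjustment, with the other tests as they were. Of 11 tests of ontology terms, 0 passed after adjustment and 2 before it. The lowest was for phosphorylation in full rehydration, with 8 higher and 1 lower (Fisher's exact p = 0.00991, adjusted p = 0.109). The other was for protein kinase activity there, with 8 and 2 (Fisher's exact p = 0.0370, adjusted p = 0.204). Both counts hold Pp1s332_14V6 and Pp1s332_17V6, which were higher in the same region and were counted separately. The terms tested in partial rehydration were too small to pass towards lower, since most genes there were lower. Those in moderate dehydration were too small to pass towards higher.

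Regions of full rehydration lay nearer to the starts of their scaffolds than those of the other comparisons. Median starts were 93376.5 for full rehydration, 447164 for moderate dehydration, 289880 for severe dehydration and 227352 for partial rehydration. On scaffolds numbered 1 to 100, 1 of 42 full rehydration regions (2.38%) began beyond 500000, against 23 of 36 of the rest (63.9%; Fisher's exact p = 1.24e-09). With scaffold number held in classes, the difference in log10 start was -0.396, or 2.49 times nearer (permutation p = 1e-05, the smallest that 100000 permutations can give). Merging overlapping regions left 118 loci of the 132 full rehydration regions, with a difference of -0.400.

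**Figure D3:**
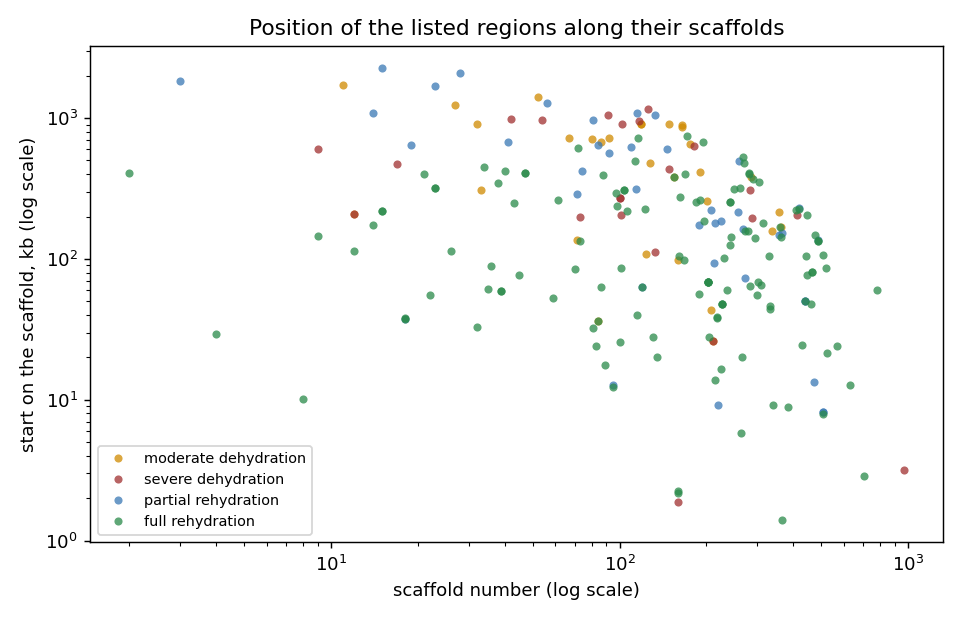
Start of each region on its scaffold in kb (y axis, log scale) by scaffold number (x axis, log scale), coloured by the comparison, from the authors' deposited table. On scaffolds 1 to 100, 1 of 42 full rehydration regions and 23 of 36 others begin beyond 500000 bases.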

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

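Apart from the binomial test of direction within a comparison, the tests in this part were chosen after the table was seen, and what each explanation predicts was written down only after the test values were known.

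The share of regions higher than hydrated differed between comparisons, tested as a difference. Partial rehydration lay 57.5 points below moderate dehydration, 42.0 points below severe dehydration and, as partial minus full rehydration, -43.6 points from full rehydration. A hydrated library with high levels would make the regions of every comparison lower, but 30% of the moderate dehydration regions were lower (95% exact interval 14.7 to 49.4), although the departure of that share from equal shares did not hold after correction. Repeated counting of a few loci is argued against as well, since 89.5% of loci were lower after overlapping regions were merged. A state of partial rehydration with lower methylation cannot be told apart from a property of its library, since there was 1 library of this state. No calling threshold or depth is known that could be tested.

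Full rehydration regions lay near scaffold starts, with a difference in log10 start of -0.396 from the rest. A different mix of scaffolds is argued against by the scaffolds that hold both kinds, where full rehydration was nearer on 25 of 27 untied scaffolds (exact sign test p = 5.65e-06). Several overlapping regions at a few loci are argued against by a difference of -0.400 after merging. A search that stopped at a fixed distance stays open: on scaffolds 1 to 100, 81.6% of 38 full rehydration loci lay in the nearer 50% of the span up to 746003, the furthest start on any scaffold, against 10 of 21 loci of the rest (Fisher's exact p = 0.00928), but with the span ended at 614936, the furthest start on these scaffolds, the counts were 29 of 37 and 10 of 14 (Fisher's exact p = 0.715). The state of full rehydration itself cannot be told apart from the handling of this 1 library, since there was no other library of this state.

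Levels of 0 made up 14.4% of the full rehydration regions, above the share in the other comparisons. A shallow full rehydration library was predicted to put them in that library. In 8 of the 19 regions it was the hydrated library that was at 0, against 0 in the other comparisons. This does not decide on a shallow library. Few reads there could also give a high level by chance and so pick out regions where the hydrated library is at 0, and the depth is unknown. Shorter regions are not decided, since regions with a level of 0 differed by -7 bases in median length (permutation p = 0.925). The hydrated library, common to all comparisons, was at 0 more often here (Fisher's exact p = 0.0223), which other calling settings in this comparison or a gain of methylation at unmethylated sites would both give. These cannot be told apart without coverage.

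Genes listed in opposite directions between partial and full rehydration were not tested for a difference. In the authors' deposited table, Pp1s489_26V6 stood at -1.06 after partial rehydration, from 135305 to 135598 on scaffold 489, and at 1.04 after full rehydration in a separate region from 134185 to 134392. The RPM1-like resistance gene Pp1s508_5V6 and its neighbour Pp1s508_6V6 shared adjacent regions on scaffold 508 that meet at base 8173, at -1.26 from 8173 to 8558 after partial and 1.04 from 7943 to 8173 after full rehydration, in the authors' deposited table. The RPS2-like resistance gene Pp1s95_7V6 had overlapping regions on scaffold 95, at -1.52 from 12817 to 13055 and at 1.95 from 12376 to 12922, in the authors' deposited table.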

How the results depend on the processing

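A stricter p or q value and other coverage minima, which had been planned, were not run, since the table has neither, and the depth of the libraries limits every value to an unknown extent. The excess of lower regions in partial rehydration stayed past the exact binomial test under all alternatives that were run, and no list or ontology term passed under any. Some of these lists and terms were too small to pass. Of 61 alternative values, 52 kept their direction and side of the threshold, or their interval. Some of the 52 could not change, since the filter removed no region. These were severe dehydration without regions with a level of 0, and full rehydration within the span of its own calls. Another 5 were shares of exactly 50%, which have no direction: severe dehydration with 1 value per gene, with annotated genes alone and with recovered levels at least 20 points apart, and moderate dehydration and full rehydration under the last of these. With only regions linked to an annotated gene, 45.8% of the full rehydration regions were higher, which turned the direction of a split that passed no test either way, and the cause was not tested. Without regions with a level of 0, chosen after seeing the data, 75% of the moderate dehydration regions were higher and the exact binomial test passed (adjusted p = 0.0251), but both regions removed were lower, so this filter could only raise the share. The adjusted p under the other alternatives ran from 0.0923 to 1, the last with the 4 regions whose recovered levels differ by at least 20 points, of which 50% were higher. For partial rehydration the adjusted p ran up to 0.0469, over the 11 regions left by that filter. Within the span of the full rehydration calls, also chosen after seeing the data, 75% of the 16 severe dehydration regions left were higher, against 54.5% of all, and the exact binomial test passed for neither (adjusted p = 0.104 within the span). The median size in partial rehydration moved to 1.14 with a pseudocount of 0.01 on recovered levels and to 1.16 on recovered levels without one, the latter chosen after seeing the data, and both rest on the 11 regions with recovered levels.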

Other observations

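Genes for AP2/ERF factors, a family of plant transcription factors many of which respond to stress hormones, were picked out after their values were seen and lie outside the fixed lists in part. All 3 such genes in the table were lower in each of their 4 entries. In the authors' deposited table, Pp1s11_198V6 stood at -1.14 after moderate dehydration, Pp1s133_11V6 at -1.58 after severe dehydration, and Pp1s120_13V6 at -1.58 after partial and -4.07 after full rehydration. With 3 genes, no test of a direction was made.

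Resistance genes annotated as RPS2 went in both directions. The resistance list did not pass the test against the other entries in either rehydration comparison. With 5 entries in each, it could not have passed towards lower in either. In full rehydration it could not have passed towards higher after adjustment, with the other tests as they were. These tests therefore decide nothing about a lean of the list towards lower. In the authors' deposited table, Pp1s14_170V6 stood at -1.42 in its body after partial rehydration, on scaffold 14 from 1087742 to 1088609. The gene Pp1s18_7V6 was lower in both rehydration comparisons, at -1.32 after partial rehydration in the authors' deposited table, while Pp1s95_7V6 stood at 1.95 after full rehydration.

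The next genes were named by the size of their change, except Pp1s282_60V6, which was added after its values were seen because it has the same annotation as Pp1s162_56V6. A lipoic acid synthetase gene (Pp1s190_51V6), which makes an enzyme cofactor, stood at 1.29 downstream after moderate dehydration in the authors' deposited table. Of the genes annotated as MOB1, a kinase partner in cell division, Pp1s162_56V6 stood at 2.12 in its body after full rehydration and Pp1s282_60V6 at -1.09 upstream and -1.39 downstream, in the authors' deposited table.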
